A study of Homo sapiens with 4 samples.

How the data were processed

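H3K4me3 chromatin immunoprecipitation followed by sequencing was carried out by the authors in control and ARID1A knockout MDA-MB-231 cells, with 1 immunoprecipitate (IP) and 1 input library per genotype. Per the labels' protocols, chromatin was digested with micrococcal nuclease and the recovered DNA was made into libraries with a kit for very small amounts of DNA. The libraries were grouped by their titles. The header of the knockout list names its library K6, a name that none of the labels used here carries, and the list was matched to the knockout by its name alone. The cell line labels of 3 libraries end in other numbers than the name in the series title, which was used here. The input libraries carry IgG as their antibody label although they are described as input, and which of these they are was not settled.

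The submitters' processing notes name Bowtie2 2.2.4, MACS 1.4.3 and the hg19 assembly. Per the file headers, the aligned tags came from sequences whose names carry cutadapt, an adapter trimmer, and Bowtie2, and MACS was run on each IP against the input of the same genotype with a p cutoff of 0.0001, an effective genome of 2.7e+09 bp, a band width of 300 bp, a model fold range of 10 to 30, local background over 1000 and 10000 bp, a tag size of 150 bp and a fragment length (d) of 300 bp. The larger of IP and input was scaled down to the smaller, per the file headers. That was the IP for the control and the input for the knockout, so fold enrichments are not on a common scale between the lists. The headers give the total tags of each library and no number after removal of duplicates. Whether duplicate tags were removed at an earlier step is not given in the sources used here. Each list comes from 1 IP library, with no pooling.

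The deposited tag counts are whole numbers of IP tags within each peak, not normalized. The deposited score, 10 times the negative log10 of the MACS p, has a ceiling of 3100, and its column name was lost, so it was identified by its place in the MACS table and by its minimum of 40, which matches the p cutoff. The deposited fold enrichment is the ratio of IP tags to the local background that MACS derived from the input. The deposited false discovery rate is in percent, from the exchange of IP and input by MACS. Positions, widths and summit offsets are in bp, and start and end were checked to be 1-based and inclusive against the deposited widths. Scores, fold enrichments and percentages were used only to filter or rank peaks within a list. Every peak of both lists was used.

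Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks were counted as overlapping when they shared at least 1 bp, and the overlap counts were checked against bedtools 2.31.1. Shares are given with exact Clopper-Pearson 95% intervals and tag counts with exact Poisson intervals. A count of 0 allows up to 3 counts of the total. With 13391724 and 27748061 IP tags these intervals are narrow, and they leave out the variation between cultures and libraries. Control peaks were ranked by tags and placed in 10 equal groups. For a chance level, the knockout peaks were moved by a random offset along each chromosome, 100 times with a fixed seed. Peaks that overlapped exactly 1 peak of the other list in each direction were compared by log2 of knockout over control tags, with a pseudocount of 1, centred on the median, because depth and enrichment differ between the libraries. Their intervals come from the binomial distribution of the knockout tags given both counts. On simulated data for 7552 peaks, 200 of them changed 4-fold in either direction, the ratio step gave the simulated sign for all 200. The median error was -0.0019 on the log2 scale. The simulated knockout counts followed the control tags with Poisson error only, without the spread of the real ratios (SD 1.96). The simulation therefore checked the arithmetic and not whether a 4-fold change can be detected in these data. No test of the genotype was made, because each genotype has 1 IP library, and no p-value is given.

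The rule for the regions named in the text was set before the data were examined, as were the alternatives, except where the closing section says otherwise. The rule takes the 10 peaks with the most tags among those found in 1 list only, for each list, the 5 highest and 5 lowest centred ratios with at least 50 tags in both lists together and an interval that leaves out 0, and the 3 widest peaks of each list. The alternatives were stricter thresholds, lists of equal length, other overlap criteria, merging of close peaks, other scalings and pseudocounts of the ratio, and another width limit. The counts of peaks of exactly 300 bp and of 450 bp to just under 500 bp, the 10 kb class, the rotations, the distances between summits, the rank correlation of tags and the values by chromosome were added after the data were examined.

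The comparisons of promoters, of the genomic location of peaks and of gene lists that had been planned were not run, because they need a gene annotation in hg19 coordinates and the annotation at hand was in GRCh38. Regions are therefore named by their hg19 coordinates.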

Results

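Trimethylation of lysine 4 of histone H3 (H3K4me3), a mark found mainly at active promoters, was profiled by chromatin immunoprecipitation and sequencing in MDA-MB-231 cells, an established triple-negative breast cancer line. The question was how the mark is distributed in cells that lack ARID1A, a DNA-binding subunit of the SWI/SNF chromatin remodelling complex, compared with control cells. There was 1 H3K4me3 library and 1 input library for each genotype, 4 libraries in all. The control immunoprecipitate (IP) held 27748061 tags and its input 14878873. The knockout IP held 13391724 tags and its input 17890122. Each genotype was represented by 1 list of peaks called against its own input, in hg19 coordinates. With no replicates, no difference between the genotypes had a replicate check, and every interval below covers counting error only. The sources used here mention no molecular identifiers, so copies of 1 fragment count as separate tags in these intervals. The state of the ARID1A gene itself was not analysed here, because a promoter mark at that locus would not show whether the protein is absent.

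The control cells carried broad H3K4me3 domains, and the knockout list held narrow peaks of about the size of a single fragment. The control list had 36677 peaks with a median width of 2968 bp (quartiles 1920 and 4932 bp). The knockout list had 23588 peaks with a median width of 300 bp (quartiles 300 and 473 bp). Together the control peaks covered 139.2 Mb, which is 5.16% of the effective genome, at a mean width of 3795 bp. The knockout peaks covered 10.3 Mb, or 0.383%, at a mean width of 438 bp. Domains of at least 4 kb made up 12887 of the control peaks (35.1%, exact Clopper-Pearson 95% interval 34.6 to 35.6%) and 3 of the knockout peaks (0.0127%, 0.00262 to 0.0372%). At a limit of 2 kb the numbers were 26610 and 34. The difference in median width was present on all 23 of chromosomes 1 to 22 and X, where the control median lay between 2402 and 4317 bp and the knockout median was 300 bp on each.

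A width of exactly 300 bp, the fragment length that the peak caller used for both lists, was found for 12977 knockout peaks (55.0%, 54.4 to 55.7%). In each of these 12977 peaks the summit lay at the centre. None of the 36677 control peaks had this width, which allows a share of up to 0.00818%, and the narrowest control peak spanned 453 bp. Another 5144 knockout peaks (21.8%) were from 450 bp to just under 500 bp wide, against 47 control peaks (0.128%). Without its 300 bp peaks, the knockout list held 10611 peaks over 6.44 Mb, with a median width of 479 bp.

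**Figure D1:**
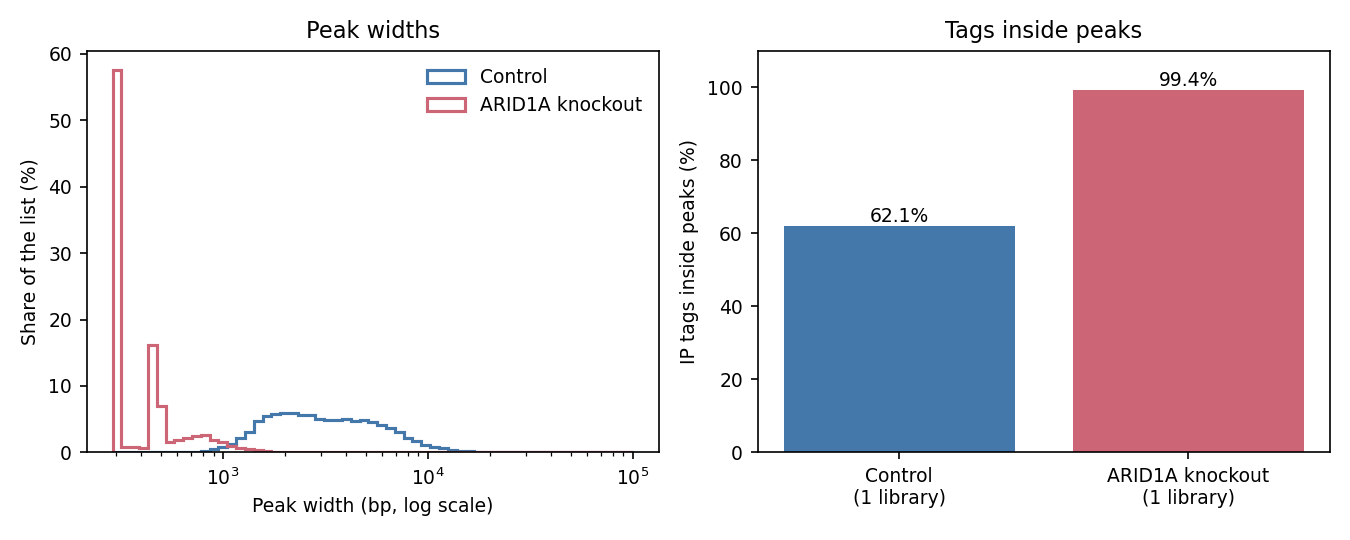
Left, the distribution of peak widths (bp, log scale) as a share of each list (%) for the control and the ARID1A knockout. Right, the share of the tags of each H3K4me3 library that lay inside its own peaks (%), 1 library per bar. The knockout widths form a spike at 300 bp while the control widths spread around a median of 2968 bp, and 99.4% of knockout tags against 62.1% of control tags lay in peaks.

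Although the knockout peaks were narrow, their median tag count over the whole list was higher. The median was 419 tags per knockout peak (quartiles 183 and 759) and 168 per control peak (quartiles 76 and 675). Across the 7552 shared peaks described below, the raw medians ran the other way, at 480 knockout and 762 control tags. Of the 13391724 tags of the knockout IP, 13307723 lay in peaks (99.4%, 99.37 to 99.38%), which left 84001 tags for the rest of the genome. Of the 27748061 tags of the control IP, 17235561 lay in peaks (62.1%, 62.10 to 62.13%) and 10512500 outside. Over the length covered, the mean tag density was 1288 tags per kb in the knockout peaks and 124 tags per kb in the control peaks. The peak caller's score reached its ceiling of 3100 for 18883 knockout peaks (80.1%) and 6804 control peaks (18.6%), so scores could not rank the stronger knockout peaks.

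The positions of the knockout peaks followed the control domains far more often than position alone would give. Of the 23588 knockout peaks, 14231 shared at least 1 bp with a control peak (60.3%, 59.7 to 61.0%). When the knockout list was rotated at random along each chromosome, 6.001% of its peaks met a control peak on average, with a range of 5.41 to 6.84% over 100 rotations, so the observed share was 10.1 times that mean. The other 9357 knockout peaks met none. In the opposite direction, 10427 of the 36677 control peaks held a knockout peak (28.4%, 28.0 to 28.9%), and 26250 held none. Because a 300 bp peak cannot cover a domain of several kb, this share depended on the overlap asked for. Only 19 control peaks (0.0518%) were covered over at least 50% of their width. With both lists limited to a false discovery rate of 1% or less, which left 20009 control and 22563 knockout peaks, the share was 46.1%. With all control peaks kept, it was 17.2% when only knockout peaks wider than 300 bp were counted.

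The overlap was higher for stronger and wider control domains. With the control peaks in 10 equal groups by tag count, 2.48% (2.002 to 3.04%) of the weakest group, which had a median of 42 tags, held a knockout peak. In the sixth group the share was 15.7% (14.5 to 16.9%) at a median of 207 tags. In the strongest group, with a median of 1716 tags, it was 84.2% (83.0 to 85.4%), which left 15.8% of the strongest control domains with no knockout peak. Control domains under 4 kb held a knockout peak in 11.1% of cases (10.7 to 11.5%), those of 4 kb or more in 60.4% (59.6 to 61.3%), and the 1079 domains of 10 kb or more in 84.4% (82.1 to 86.5%). A total of 2861 control domains held 2 or more separate knockout peaks, with a maximum of 9 in 1 domain. Inside the control domains the knockout summits lay near the control summits, at a median distance of 568 bp. A distance of at most 500 bp was found for 46.0% of these 14231 knockout peaks, against 19.4% for positions spread evenly over the same domains.

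**Figure D2:**
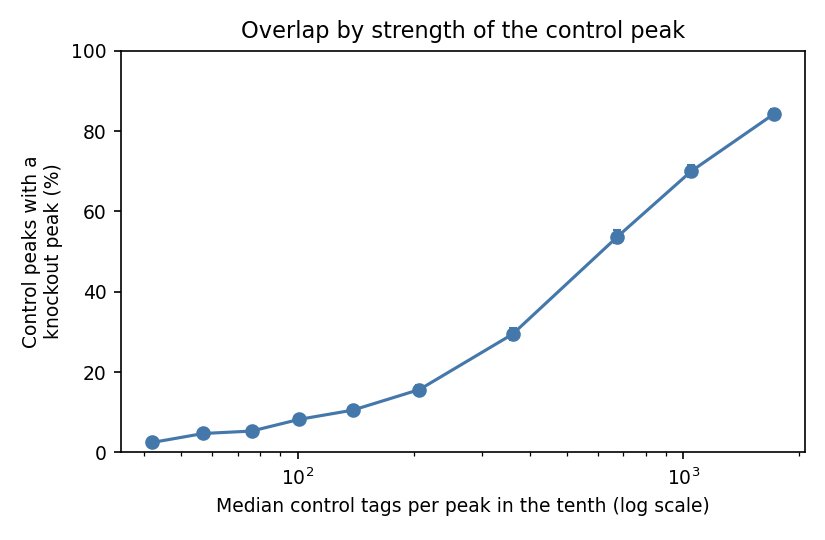
Share of control H3K4me3 peaks that held a knockout peak (%), for the control peaks in 10 equal groups by their own tag count, plotted at the median control tags per peak (log scale). Bars are exact 95% intervals for counting error and are mostly smaller than the points. The share goes from 2.48% in the weakest group to 84.2% in the strongest.

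The widest control domain lay on chromosome 5, from 14138379 to 14210925, and spanned 72547 bp with 14620 tags (exact Poisson interval 14384 to 14859). The knockout list held 7 separate peaks within it, with 4682 tags together. The next widest control domains, on chromosome 19 from 1231600 to 1279509 and on chromosome 11 from 62303834 to 62345746, spanned 47910 and 41913 bp. They held 6 and 7 knockout peaks, with 5446 and 4830 knockout tags. The 3 widest knockout peaks were in a different part of the genome, close together on chromosome 1. They ran from 228748071 to 228753012 with 963 tags, from 228765325 to 228778435 with 3349 tags and from 228778744 to 228783756 with 2564 tags. The nearest control peak to any of them was 58128 bp away. The gene content of these regions was not analysed here, nor whether the chromosome 1 stretch holds repeated sequence, in which the placement of tags is uncertain.

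Some strong control domains had no knockout peak at all. The strongest of them lay on chromosome 12, from 122226059 to 122252014, with 5524 tags (5379 to 5672) over 25956 bp, and the nearest knockout peak was 57351 bp away. It was followed by domains on chromosome 4 from 41359671 to 41368289 with 3756 tags, on chromosome 2 from 110360280 to 110376517 with 3577 tags and on chromosome 11 from 66883691 to 66894496 with 3531 tags. A second domain on chromosome 4, from 39452885 to 39463797, held 3529 tags. The remaining 5 of the 10 strongest, on chromosomes 10, 20, 5, 5 and 14, held between 3182 and 3465 tags. As a group, the control peaks without a knockout peak were weak, with a median of 110 tags and a median width of 2384 bp, against 921 tags and 5464 bp for those with one.

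Knockout peaks outside the control domains were narrow and tag-rich as well. Apart from the chromosome 1 stretch described above, the most tags were found on chromosome X from 149204002 to 149204457, with 3003 tags (2897 to 3112) in 456 bp, 77 bp from the nearest control peak. On chromosome 1 a peak from 239993516 to 239993981 held 2946 tags in 466 bp and lay 199566 bp from any control peak. Further peaks of this kind were on chromosome 12 from 54059627 to 54060101 with 2828 tags, on chromosome 4 from 5259199 to 5259653 with 2710 tags and on chromosome 2 from 118787550 to 118788029 with 2590 tags. The 9357 knockout peaks outside control domains had a median of 336 tags (quartiles 138 and 610), and the 14231 inside had a median of 482 (quartiles 226 and 874). Among peaks of exactly 300 bp the medians were 291 tags outside and 338 inside. Among wider knockout peaks they were 496 tags outside and 714 inside.

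Where 1 knockout peak matched 1 control peak, the tag counts of the libraries ranked only weakly together. Across these 7552 shared peaks, Spearman's rho between control and knockout tags was 0.19, a correlation across regions, which are not independent replicates. These pairs leave out the control domains with no knockout peak and the 2861 with 2 or more. Over all control peaks, the share that held a knockout peak rose with the control tags, as given above. For the shared peaks, the log2 ratio of knockout to control tags, centred on its median, had an SD of 1.96. Of its values 90% lay between -3.60 and 3.09. The counting interval left out 0 for 6935 of the 7552 peaks (91.8%), of which 3491 were above and 3444 below the median. Centring on the median makes this split near even, so it gives no direction. Copies of 1 fragment count as separate tags in the counting interval, so the 91.8% does not measure how many regions differ. Before centring, the median on the log2 scale was -0.46 for raw tags and 0.60 when tags were divided by the total of each library. Raw tag density per kb was a median of 8.38 times higher in the knockout peak than in its control partner. After division by the library totals it was a median of 17.4 times higher. The control peaks of these pairs were a median of 4915.5 bp wide and the knockout peaks 330.5 bp.

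The most extreme ratios paired a tag-rich knockout peak with a weak control peak, or a few knockout tags with a strong control domain. The highest was on chromosome 14 at the control peak from 65672961 to 65674823, with 3122 knockout tags over 1114 bp, 51 control tags and a centred log2 ratio of 6.36 (5.99 to 6.82). The second highest, on chromosome 2 from 38917183 to 38918211, had 2142 knockout and 41 control tags, for a ratio of 6.13 (5.72 to 6.65). At the other end, the control domain on chromosome 20 from 33861874 to 33876016 held 3609 control tags and a single 300 bp knockout peak with 16 tags, for a ratio of -7.27 (-8.17 to -6.66). On chromosome 9, from 100450360 to 100468716, 2448 control tags stood against 15 knockout tags, for a ratio of -6.80 (-7.73 to -6.17). The remaining 3 peaks at each end had ratios of 5.71 to 6.05, on chromosomes 17, 11 and 4, and of -6.67 to -6.54, on chromosomes 6, 1 and 1. These sizes depend on the different widths of the paired peaks. Per kb of peak width the 5 highest were 3.58 to 4.19 and the 5 lowest -6.01 to -4.39. Among the 5 highest, the pairs on chromosomes 17 and 11 overlapped only at an edge. On chromosome 17 the control peak ended at 54451372 and the knockout peak, with 1884 tags, ran from 54451336 to 54451788. On chromosome 11 the control peak ended at 8955349 and the knockout peak, with 1821 tags, ran from 8955302 to 8955764. Most of each of these knockout peaks lay outside its control peak, so their ratios compare largely different stretches.

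Chromosomes 1 to 22 and X differed in how much of the control landscape was met. Chromosome 19, where the control peaks were strongest with a median of 515 tags and widest with a median of 4317 bp, had the highest share of control peaks with a knockout peak, at 50.1% (47.6 to 52.6%). Chromosome 13, with a control median of 117 tags and 2402 bp, had the lowest, at 18.9% (16.4 to 21.6%). Among the same 23 chromosomes the share of knockout peaks inside control peaks ran from 47.2% (42.1 to 52.4%) on chromosome 18 to 72.3% (70.1 to 74.5%) on chromosome 19. The knockout list had fewer peaks than the control list on 22 of the 23, with chromosome 19 the exception at 1576 knockout and 1555 control peaks.

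**Figure D3:**
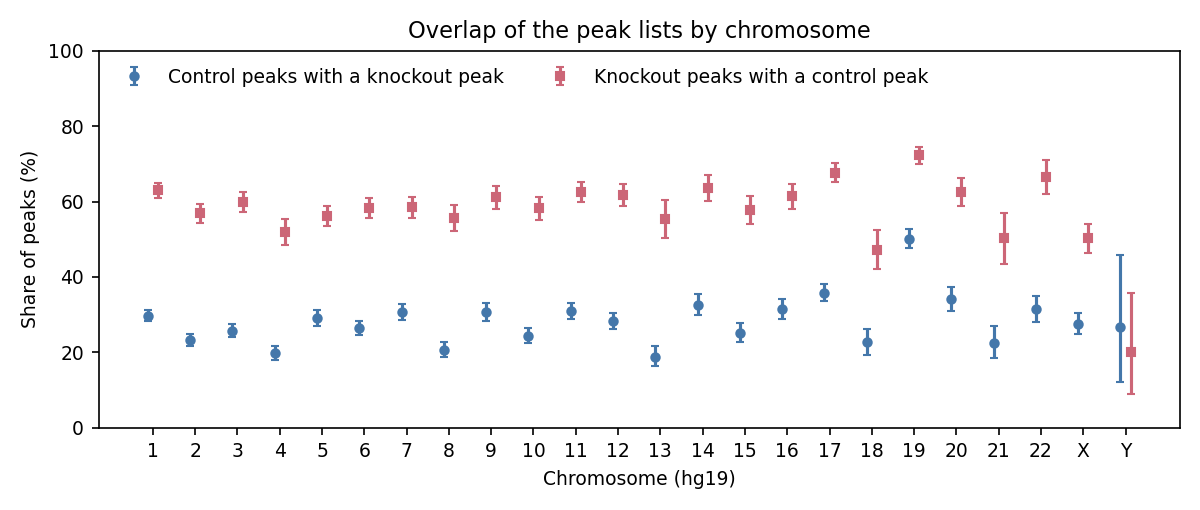
Share of control peaks that held a knockout peak (circles) and share of knockout peaks that met a control peak (squares), in %, for each chromosome. Bars are exact 95% intervals for counting error, 1 library per genotype. Chromosome 19 stands highest in both shares, at 50.1% and 72.3%.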

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

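The alternative that kept only knockout peaks wider than 300 bp was chosen after seeing the data, and the others before the data were examined. Counts and lengths were taken as kept within 1.5 times, shares within their counting interval. The 40 recomputed ratios of the named shared peaks all kept their sign, but 14 left their counting interval: 5 of the highest after division by the library totals (6.31 to 6.96), and 9 per kb of peak width, where the highest were 3.58 to 4.19 and the lowest -6.01 to -4.39. Of the other alternative values 24 moved, as follows. The share of control peaks with a knockout peak, 28.4% as reported, was 37.7% with a MACS p of 1e-10 or less, 29.3% with a fold enrichment of 10 or more, 46.1% with an FDR of 1% or less, 41.4% with lists of equal length, 29.98% with a peak within 1 kb, 0.0518% with an overlap of 50% of the peak or of both peaks, and 17.2% with only knockout peaks wider than 300 bp. The share of knockout peaks with a control peak, 60.3% as reported, was 58.5%, 56.8% and 57.5% under the p, FDR and equal-length settings, 59.6% with 50% of the peak, 0.0805% with 50% of both, 63.3% within 1 kb, and 70.6% with only peaks wider than 300 bp. The reciprocal criterion compares peaks of very different width, which by construction leaves 19 pairs. The control list had 20009 peaks at an FDR of 1% or less and 23588 at equal length. The knockout list without its 300 bp peaks had 10611 peaks over 6.44 Mb with a median width of 479 bp. Peaks of at least 2 kb in place of 4 kb numbered 26610 in the control and 34 in the knockout, and merging peaks within 1 kb gave 12 knockout peaks of at least 4 kb. The median log2 ratio was 0.60 after division by the library totals, uncentred, where centring sets it to 0. For the other shifts the cause was not tested. Alternatives for promoters, genomic location and gene lists were not run, for want of an hg19 annotation. The knockout depth of 13391724 tags is no guide to its precision where tags are copies of 1 fragment.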

Other observations

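Relative to the control tags on each chromosome, the knockout peaks inside control domains were not spread evenly over chromosomes 1 to 22 and X. On chromosome X, 345 such peaks stood against 227 expected from the control tags, a ratio of 1.52 (exact Poisson interval 1.36 to 1.69). Chromosomes 7 and 19 followed with ratios of 1.27 (1.18 to 1.36) and 1.25 (1.17 to 1.32). The lowest ratios were on chromosomes 8, 20 and 13, at 0.79 (0.72 to 0.87), 0.81 (0.74 to 0.89) and 0.82 (0.72 to 0.94). Chromosome Y, with 8 such peaks, had a ratio of 2.02 (0.87 to 3.97). These intervals cover counting error only, and 1 library per genotype cannot separate a genotype from a difference between cultures or clones. The knockout list had 4 peaks of at least 3 kb, singled out after their values were seen, all within 35.7 kb of chromosome 1 between 228748071 and 228783756 with 7699 tags together, and no control peak met any of them.

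The tests below were chosen after the results they bear on, or closely related ones, had been seen, except the rank correlation of tags and the simulated merging of draws, whose bounds were set before they were computed. They were all found and run on the same lists, so what they favour remains a hypothesis.

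The first pattern is that 99.4% of the knockout tags lay in narrow peaks. Lower sequencing depth is argued against as the whole cause, because random thinning would not raise the share of tags in called peaks above the 62.1% of the control. Narrower H3K4me3 domains in the knockout cells are argued against as the whole cause, because nucleosome fragments of a narrow domain still start at many positions, while 55.0% of the peaks had exactly the width and central summit that a stack of tags at 1 position would give. A candidate explanation that the values favour is a knockout library made of few distinct fragments, each copied many times. This may happen with very little starting DNA. Besides the 55.0%, the tags of shared peaks ranked little with the control (rho 0.191, below the bound set beforehand). That rho leaves out control domains with no knockout peak or with several, and the share with a knockout peak rose with the control tags. The 300 bp peaks inside control domains held 1.16 times the median tags of those outside. They are the same peaks as the 55.0%, so this is not separate support. Among wider knockout peaks the medians were 714 tags inside and 496 outside. The headers record no removal of duplicates, so a different handling of them in the control stays open.

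The second pattern is that 26250 control peaks had no knockout peak. Random draws were made in proportion to control tags, as many as there were knockout peaks in control domains. The observed number of domains with a peak was 12.2% higher, which argues against draws that each give a separate peak. Where close draws merge into 1 peak, the draws outnumber the peaks, so this comparison does not test that case. With the draws fitted to the observed number, the largest deviation of the 10 groups by control tags was 5.44 percentage points. Domains with 2 or more peaks numbered 2861 against 3900 from these draws, so this form, also without merging, is argued against too. Draws were then placed around the control summits and merged where 300 bp stretches touched. The number with 2 or more was 3294 (3209 to 3376 over 20 simulations), closer but outside the bound of 10%. Since the placement and the 300 bp stretch were assumed, a chance draw with merging stays open. A loss of H3K4me3 at some or most control peaks cannot be told apart from such a draw, because there is 1 knockout library. In the strongest group 15.8% had no knockout peak, against 17.1% from the fitted draws. The 60.3% of knockout peaks inside control domains does not decide. Random draws of control tags would give a similar share, since 62.1% of the control tags lay in control peaks.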
